A study of Drosophila melanogaster with 9 samples.

How the data were processed

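Gene expression was measured by the authors on 9 Affymetrix Drosophila_2 arrays, 3 from wild type, 3 from an OGA mutant and 3 from an SXC mutant, numbered 1 to 3 in each group. The deposited values are on a log2 scale, with 1 value per probe set and array; their scale was read from the values themselves, which were positive and had nearly equal quartiles on all arrays. The processing notes of the submitters name MAS5, RMA and Partek with no role or version, and which of these made the deposited values is not given in the sources used here. The labels give no tissue, stage, allele, RNA preparation date or array batch, and no detection calls were used. All sample columns mapped to a group (0 unmapped).

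The table held 18952 probe sets, of which 183 were controls and were left out of the tests of genes. A table of the array's probe sets and their genes paired 13647 probe sets with 1 gene, 402 with several genes and 4720 with none listed. Probe sets not listed with a single gene are called unnamed here. Older gene symbols were updated through the Entrez gene identifier. Gene names, lengths and neighbours came from a RefSeq annotation of the Drosophila melanogaster assembly Release 6 plus ISO1 MT; no coordinates of it are printed, and 103 probe sets with 1 gene had a gene that is not in that annotation. Where a gene had more than 1 probe set (1094 genes), the probe set with the highest mean over the 9 arrays was used, which left 11982 genes.

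Groups were compared in R 4.3.3 with limma 3.58.1, by a model of group means over all 9 arrays (6 residual degrees of freedom, 5.17 prior degrees of freedom) and moderated statistics with a constant prior. The contrasts were OGA mutant against wild type, SXC mutant against wild type and OGA mutant against SXC mutant. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called changed, with no minimum size. The median SE of a log2 change was 0.08. The number of arrays limits the precision of all estimates. The comparisons, the main alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

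The rule for named genes took Oga and sxc in each contrast, and the 10 largest rises and 10 largest falls against wild type (5 and 5 between the mutants). These had to be called, have arrays of the groups that did not overlap, and have a mean in the brighter group above the median over genes tested (7.50). It also took up to 4 called members of each list with the smallest p (or, where a list passed with no called member, those with the smallest p as values), and allowed any member of the lists on O-GlcNAc cycling, the Polycomb group, Hox genes and eye colour. Klc falls outside the rule.

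The 34 gene lists, with 1123 members of which 887 were measured, cover O-GlcNAc cycling and the hexosamine pathway, the Polycomb and Trithorax groups, Hox genes and other Polycomb targets, heterochromatin, eggshell, yolk, germline, testis, accessory gland and dosage compensation. They also cover insulin and TOR signalling, glycolysis, lipids, digestion, heat shock, endoplasmic reticulum stress, immunity, detoxification, ecdysone, larval serum and fat body, cuticle, neurons, photoreceptors, eye colour, muscle, haemocytes, cell cycle, ribosome, mitochondria, odorant binding, oxidative and metal stress and the circadian clock. Each was tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast; lists with fewer than 3 measured genes were not to be tested, and all 34 were. With a correlation estimated from the data, 0 lists were called in any of the contrasts.

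The mutants share the wild-type arrays, so the covariance of their changes was compared with 100 simulations of unchanged mutants against the same controls, and was also computed with each mutant set against a different wild-type array. The simulations leave the SXC mutant unchanged, so they give no chance value for the correlation, the share of genes with the same sign or the counts of genes. They also draw genes independently with the same spread in all groups, so their range for the covariance is too narrow. Measures of single arrays were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 arrays is 0.1. The 3′ minus 5′ differences came from 5 pairs of 3′ and 5′ control probe sets. GAPDH and GAPDH_r2 are both named for GAPDH, and ACTIN and Act5C_r2 both for actin. The pairs are therefore not 5 separate transcripts. Sets of neighbouring genes used genes above the 40th percentile of mean level and were compared with 10000 random sets matched on gene length and level, with 95% bootstrap intervals from 2000 draws.

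Alternatives were quantile normalization, median centring, leaving out genes under the 25th percentile of mean level, an intensity trend with a robust prior, array quality weights, a replicate block, leaving out each array in turn, a linear model with no moderation, the most variable probe set per gene, all probe sets, a minimum of 1.5-fold, a fit of only the 2 groups compared, and for lists an estimated correlation and ranks. Removal of a trend with gene length and level from each array (loess, span 0.3), and the alternatives for the lists between the mutants, were added after the data had been seen. The full procedure was tested on simulated data with the spread of these arrays over 11982 genes. Changes of 1.25-fold, 1.5-fold and 2-fold were planted together, so the adjusted threshold was that of a contrast with many changed genes. At 1.25-fold it recovered 46.3% of 67 genes for the OGA mutant against wild type, 49.3% of 67 for the SXC mutant against wild type and 32.8% of 67 for the OGA mutant against the SXC mutant. At 1.5-fold it recovered 98.5% of 67 genes for the OGA mutant against wild type, 92.5% of 67 for the SXC mutant against wild type and 97.0% of 67 for the OGA mutant against the SXC mutant; at 2-fold it recovered 100% of 66 genes in each, with 7 false calls among 170, 7 among 168 and 4 among 157. Raw array images were not analysed here.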

Results

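Gene expression was measured in Drosophila on 9 Affymetrix Drosophila_2 arrays, 3 each from wild type, an OGA mutant and an SXC mutant. Oga encodes the O-GlcNAcase that removes O-linked N-acetylglucosamine from proteins, and sxc (super sex combs) encodes the O-GlcNAc transferase that attaches it. The title of the series links O-GlcNAcase to nutrient-responsive oogenesis; the labels name no tissue, stage or allele. The arrays had medians of 5.96 to 6.04 on the log2 scale, and the number of arrays limits the precision of every value. Values of 11982 genes were compared. Correlations across genes (which are not independent replicates) were 0.997 to 0.999 between arrays of a group and 0.993 to 0.999 between arrays of different groups. The first principal component held 52.4% of the variance and placed the SXC mutant arrays at 10.5 to 22.7, the wild-type arrays at −10.8 to −4.26 and the OGA mutant arrays at −12.3 to −5.58. SXC mutant replicate 1 lay farthest out. The p-values of single genes and of array measures rest on the spread between these arrays. That spread may be technical, because the labels do not say whether the replicates came from separate animals or cultures. The p-values of gene lists at the preset correlation set the changes of members against those of other genes. They do not measure how far a list shift varies between arrays.

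The comparison of the OGA mutant with wild type asked which transcripts changed when O-GlcNAc removal was altered. Oga (chromosome 3R) was the gene that passed the test: it had a level of 8.84 ± 0.08 (SD, n = 3) in the mutant and 9.90 ± 0.22 (SD, n = 3) in wild type. The fall was 2.07-fold, a log2 change of −1.05 with SE 0.10 (limma adjusted p = 0.00698), and all 3 mutant arrays were below all 3 wild-type arrays. sxc had a log2 difference of 0.05 with SE 0.06 (adjusted p = 0.975). Whether the Oga probes lie in the altered part of the gene is unknown. At an unadjusted p under 0.05 there were 468 genes, against 599.1 by chance, and 9.04% of genes had groups that did not overlap, against 10% by chance. In data simulated on these arrays the same test recovered 98.5% of genes given a 1.5-fold change but only 46.3% of those given a 1.25-fold change. The simulated comparison held 170 calls, which makes the adjusted threshold easier to pass than with 1 call. The recovered shares are therefore too high for this comparison. The Oga call ended without wild type replicate 3 (adjusted p = 0.0750), OGA mutant replicate 1 (0.0551), OGA mutant replicate 2 (0.05003) or OGA mutant replicate 3 (0.0627), and with no moderation of the variances (0.979). The log2 change stayed between −1.16 and −0.94 with any array left out. The count was 0 in each of these settings and when the arrays of only the 2 groups were fitted. It was 2 with an intensity trend and robust prior, where Klc, the kinesin light chain gene, was added. Klc was chosen after its values were seen (log2 0.54 with SE 0.08, adjusted p = 0.118 in the main test and 0.00674 with that prior).

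**Figure D1:**
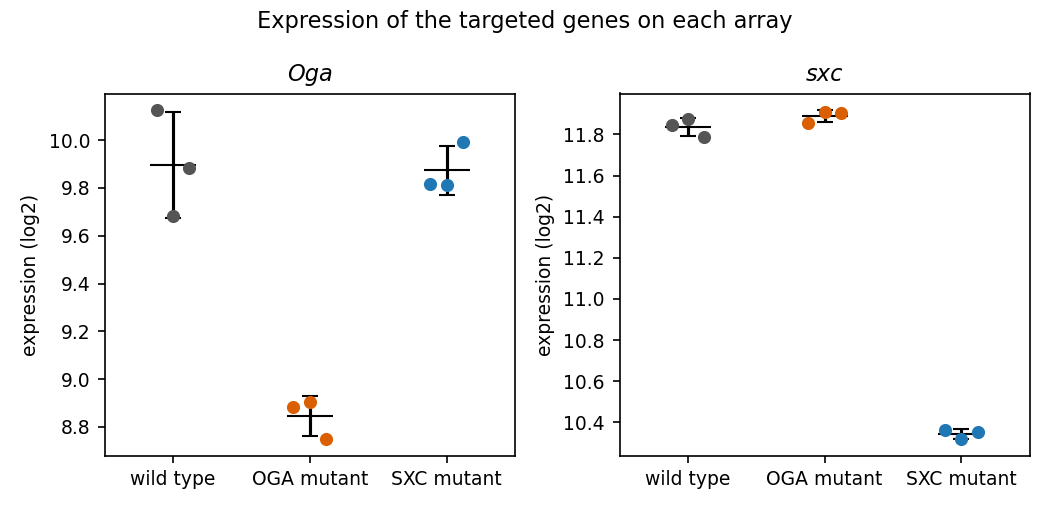
Expression of Oga (left) and sxc (right), log2 on the vertical axis, on the 3 arrays of each group; each point is an array, and black marks give the mean with the SD. Oga was lower on the OGA mutant arrays (8.84 ± 0.08) and sxc on the SXC mutant arrays (10.35 ± 0.02).

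Among the gene lists, genes of the mitochondrial respiratory chain and of antimicrobial and humoral immunity were shifted down in the OGA mutant, by small amounts. In the mitochondrial respiratory chain 58 of 75 measured genes had a negative change, with a median of −0.04 (limma camera, adjusted p = 0.00520, and adjusted p = 0.934 with an estimated correlation). No member passed, over all genes or adjusted over the list alone; the smallest p-values belonged to COX7AL (log2 −0.25 with SE 0.11) and COX4L (−0.13 with SE 0.06), both relatives of cytochrome c oxidase subunits. In antimicrobial and humoral immunity 20 of 26 measured genes had a negative change, with a median of −0.06 (adjusted p = 0.0127, and adjusted p = 0.520 with an estimated correlation). Again 0 members passed in limma, over all genes or adjusted over the list alone, and the values with the smallest p were Drsl5, a drosomycin-like peptide gene (−0.14 with SE 0.06), and dl, the NF-kappaB factor dorsal (0.13 with SE 0.06). Both lists hold short genes (median lengths of 1089 and 610.5 bp), and in the OGA mutant the change correlated with gene length across genes (r = 0.35 over 7166 genes). With the length trend removed, an alternative chosen after seeing the data, neither call was kept (adjusted p = 0.979 and 0.339). The mitochondrial median was then −0.00, while the immunity median stayed at −0.05. The mitochondrial call also ended without wild type replicate 2 (0.0521), wild type replicate 3 (0.101) or OGA mutant replicate 1 (0.339), and the immunity call without wild type replicate 2 (0.0635) or OGA mutant replicate 1 (0.126). The number of lists called was 2, but 0 without wild type replicate 2, 4 without wild type replicate 3, 1 without OGA mutant replicate 1, 5 without OGA mutant replicate 3 and 4 with array quality weights.

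The remaining lists did not pass in the OGA mutant, and Oga was their only member with a call. In O-GlcNAc cycling and the hexosamine pathway 1 of 8 measured genes fell, also when adjusted over the list alone (adjusted p = 0.908). The median was 0.04 and the test pointed up, while the mean, which Oga pulls down, was −0.07. Germline and oogenesis genes (40 measured, median 0.04, adjusted p = 0.729) and eggshell genes (19 measured, median −0.00, adjusted p = 0.643) had 0 changed members in limma, over all genes or adjusted over the list alone. The same held for yolk proteins and uptake (4 measured, median 0.08, adjusted p = 0.625) and insulin, TOR and nutrient signalling (27 measured, median 0.06, adjusted p = 0.112). The Polycomb group (19 measured, adjusted p = 0.654) and the Hox genes (4 measured, adjusted p = 0.949) had none either. The Hox genes read 4.13 to 5.47 on the 9 arrays, so their probe sets may detect no transcript. Pc, which encodes Polycomb, had a log2 difference of 0.22 (adjusted p = 0.975). Endoplasmic reticulum stress came nearest to a further call (18 measured, median 0.06, adjusted p = 0.0576), and passed when the test used ranks (adjusted p = 0.0385).

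The comparison of the SXC mutant with wild type asked the same of altered O-GlcNAc transfer, and gave changes in many more genes. sxc (chromosome 2R) fell 2.81-fold, from 11.84 ± 0.04 to 10.35 ± 0.02 (SD, n = 3 each), a log2 change of −1.49 with SE 0.06 (limma adjusted p = 2.81e-07). Oga had a log2 difference of −0.02 with SE 0.10 (adjusted p = 0.922), and whether the sxc probes lie in the altered part of that gene is unknown. In all, 1549 genes (12.9%) changed, 610 higher and 939 lower, with a median size of 0.38 on the log2 scale. A change of at least 1.5-fold was seen in 284 of them, 155 higher and 129 lower, so that rises were the larger group there, and 47 changed at least 2-fold. At an unadjusted p under 0.05 there were 3124 genes, against 599.1 by chance, and 32.7% of genes had groups that did not overlap, against 10% by chance. The number changed was 664 without wild type replicate 1, 1027 without wild type replicate 2, 896 without SXC mutant replicate 1 and 984 without SXC mutant replicate 2; it was 2824 with array quality weights and 820 with no moderation. Of the 1549 genes, 855 were also called without SXC mutant replicate 1. Of the 5 pairs of control probe sets used as a sign of RNA quality, GAPDH_r2 differed most on the SXC arrays. The 3′ minus 5′ difference of the GAPDH_r2 control probe sets was 2.78 ± 0.26 (SD, n = 3), against 2.15 ± 0.19 in wild type (exact permutation p = 0.1, the smallest the design allows) and 2.16 ± 0.13 in the OGA mutant. GAPDH was 1.15 against 0.99 in wild type (exact permutation p = 0.2). ACTIN (0.03 against 0.05), eIF4a (0.21 against 0.26) and Act5C_r2 (0.748 against 0.755) were not higher. Without GAPDH_r2, 0 SXC arrays had a mean difference above the wild-type range. That mean still held the other GAPDH pair, so it does not leave out a whole transcript. The change in the SXC mutant correlated with gene length across genes (r = 0.26 over 7166 genes), and with that trend removed 1187 genes were called, 973 of them among the 1549.

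The largest rises in the SXC mutant that met the rule for named genes were Cyt-b5-r, a cytochrome b5-related gene (log2 1.68 with SE 0.26, 3.21-fold, from 10.35 ± 0.08 to 12.03 ± 0.62, limma adjusted p = 0.00264) and CG13031 (1.64 with SE 0.30, 3.12-fold). The zona pellucida domain gene zye rose by 1.59 (SE 0.18, 3.01-fold, adjusted p = 0.000842). The genes bero (1.48), CG12991 (1.43), CG12910 (1.40), yellow-h, a yellow family gene on chromosome 4 (1.40), CG2233 (1.36), CG5246 (1.34) and CG9837 (1.32) rose 2.5-fold to 2.80-fold. The largest falls were in CG15399 (−2.001 with SE 0.22, 4.002-fold, from 9.55 ± 0.21 to 7.55 ± 0.55, adjusted p = 0.000733), CG34330 (−1.81 with SE 0.27, 3.50-fold) and CG11825 (−1.80 with SE 0.23, 3.48-fold). After sxc came Reg-2 (−1.48), Had2 (−1.37), CG16888 (−1.37), the peptide transporter yin (−1.24), the lysosomal sulfatase Ids (−1.24) and the peroxiredoxin Prx6c (−1.22), which fell 2.33-fold to 2.79-fold. The calls of CG13031, CG12991, CG2233 and CG5246 ended with no moderation (adjusted p = 0.0717, 0.0573, 0.0554 and 0.0735). Some sizes leaned on SXC mutant replicate 1, the outlying array. Cyt-b5-r read 12.75 there, against 11.67 and 11.68 on replicates 2 and 3, and CG34330 10.61, against 11.98 and 11.49. The gene zye leaned on it less (8.63, against 8.18 and 8.51). Over the alternatives, the change of Cyt-b5-r was as small as 1.33 and that of CG34330 as small as −1.43.

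**Figure D2:**
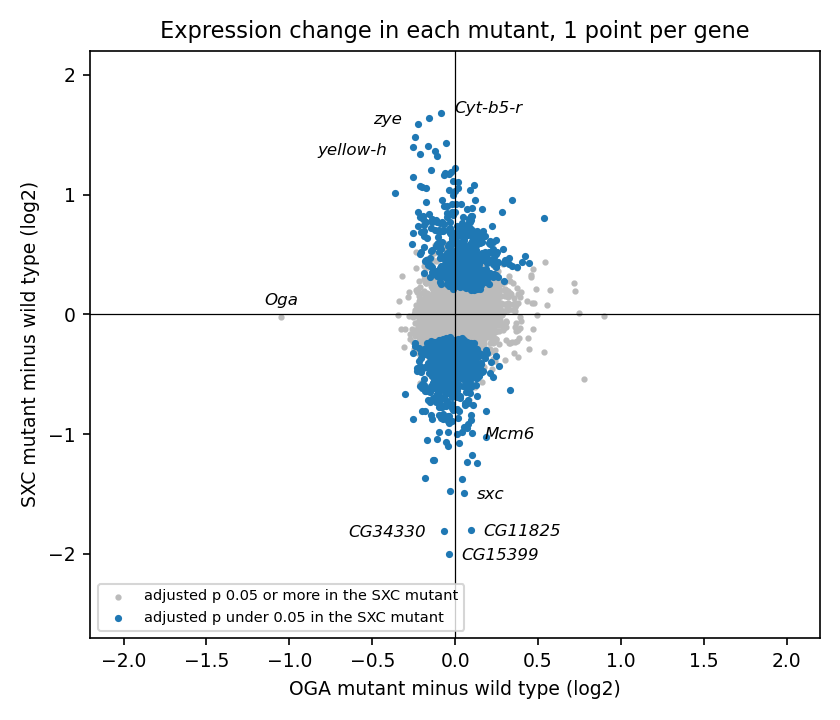
Log2 change of each gene in the OGA mutant (horizontal axis) and in the SXC mutant (vertical axis), each against wild type with 3 arrays per group; blue points are the 1549 genes called in the SXC mutant. Oga is the point at −1.05 on the horizontal axis, and sxc lies at −1.49 on the vertical axis.

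Cell cycle and DNA replication genes fell together in the SXC mutant: 17 of 36 measured members fell, 0 rose and 19 did not pass, and 25 fell when adjusted over the list alone. The median was −0.29, and 33 of 36 changes were negative (limma camera, adjusted p = 2.12e-10, and adjusted p = 0.653 with an estimated correlation). Mcm6, a subunit of the replicative helicase, fell by 0.99 on the log2 scale (SE 0.11, 1.99-fold, adjusted p = 0.000675). Cdk2, an S-phase cyclin-dependent kinase, changed by −0.83 (SE 0.14), aurB, the Aurora B kinase, by −0.60 (SE 0.11) and Psf2, of the GINS replication complex, by −0.45 (SE 0.07). Xenobiotic detoxification genes rose: 11 of 46 measured members rose, 1 fell and 34 did not pass, with 14 higher and 1 lower adjusted over the list alone. The median was 0.16 (adjusted p = 0.000104, and adjusted p = 0.653 with an estimated correlation). The cytochrome P450 genes Cyp12a5 (0.69, SE 0.13) and Cyp6w1 (0.53, SE 0.06) and the glutathione transferase gene GstE2 (0.47, SE 0.07) rose, and GstE9 fell (−0.39, SE 0.06). Among the 18 alternatives run, only the estimated correlation ended these list calls. The estimate was 0.55 for the cell cycle list and 0.16 for the detoxification list, well above the preset value. The other alternatives kept the preset value and so do not test it, and both list calls depend on it. With no moderation the calls of aurB and Cyp12a5 ended (adjusted p = 0.0570 and 0.0592).

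**Figure D3:**
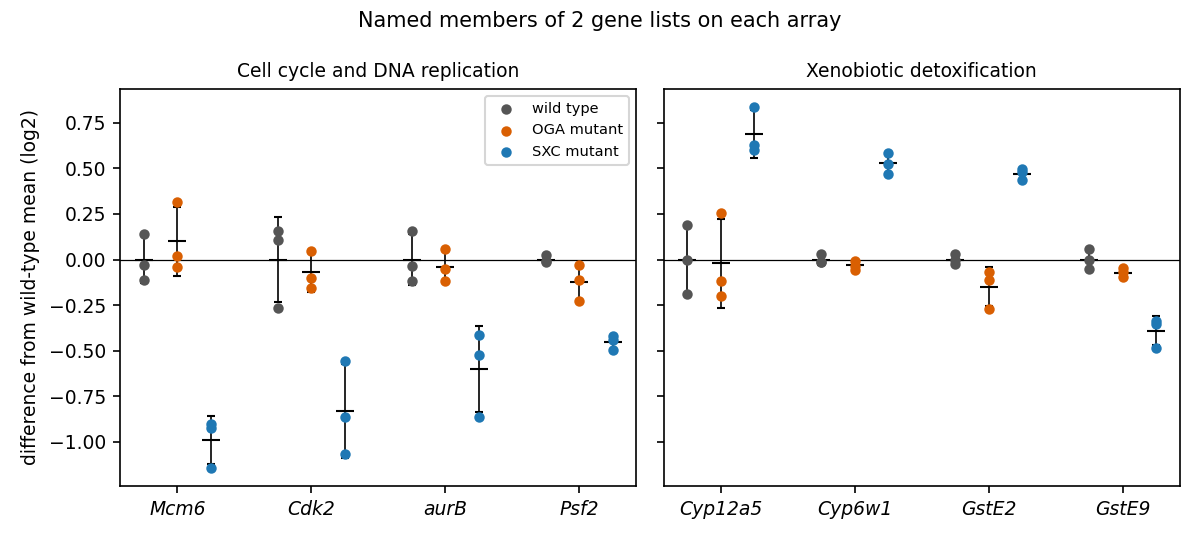
Difference from the wild-type mean (log2, vertical axis) of members of cell cycle and DNA replication (left) and xenobiotic detoxification (right) on the 3 arrays of each group; points are arrays and black marks the mean with the SD. In the SXC mutant the mean difference was −0.99 for Mcm6 and 0.53 for Cyp6w1.

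A further 4 lists were called in the SXC mutant with smaller shifts. Endoplasmic reticulum stress genes were mostly positive (16 of 18, median 0.10, limma camera adjusted p = 0.0252, and adjusted p = 0.653 with an estimated correlation). Atf6, a stress-responsive transcription factor gene that lies near sxc, was the member that rose (log2 0.38 with SE 0.10, adjusted p = 0.0258), and 1 rose adjusted over the list alone. The Atf6 call ended without wild type replicate 1 (adjusted p = 0.109), wild type replicate 2 (0.0854), or SXC mutant replicate 1 (0.0598), 2 (0.0630) or 3 (0.0711), with no moderation (0.0979) and with the length trend removed (0.0601). Mitochondrial respiratory chain genes had a median of −0.08 (adjusted p = 0.0252, and adjusted p = 0.900 with an estimated correlation), and 7 of 75 measured members fell, 0 rose and 68 did not pass, also 7 lower adjusted over the list alone. Among these were ATPsynepsilonL (−0.52, SE 0.08) and ND-B14.5A, a complex I subunit gene (−0.35, SE 0.06). In heat shock and protein folding 1 of 13 measured genes rose, also adjusted over the list alone, with a median of 0.10 (adjusted p = 0.0406, and adjusted p = 0.653 with an estimated correlation). It was stv (starvin), an Hsp70 cochaperone gene (0.34, SE 0.07). In ecdysone synthesis and response 1 of 34 measured genes rose, and 0 adjusted over the list alone, with a median of 0.06 (adjusted p = 0.0406, and adjusted p = 0.653 with an estimated correlation). It was the hormone-responsive transcription factor gene Kr-h1 (0.38, SE 0.10, adjusted p = 0.0291), whose call ended without wild type replicate 1 (0.1197), 2 (0.0590) or 3 (0.0565) or SXC mutant replicate 3 (0.0890), with no moderation (0.109) and with a replicate block (0.0571).

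The median gene length was 3840 bp in the endoplasmic reticulum stress list, 1089 bp in the mitochondrial list, 3178 bp in the heat shock list and 4831 bp in the ecdysone list. None of these 4 calls was kept with the length trend removed (limma camera adjusted p = 0.156 for endoplasmic reticulum stress, 0.455 for the mitochondrial respiratory chain, and 0.148 for both heat shock and ecdysone genes). The median then was −0.02 in the mitochondrial list, but stayed at 0.06 in the ecdysone list, and was 0.08 in the heat shock list and 0.07 in the endoplasmic reticulum stress list. Quantile normalization ended the endoplasmic reticulum stress, heat shock and ecdysone calls (adjusted p = 0.0605, 0.0605 and 0.0552), and array quality weights the heat shock and ecdysone calls (0.0928 and 0.0506). The endoplasmic reticulum stress call also ended without wild type replicate 2 (0.0549) or SXC mutant replicate 3 (0.111). The mitochondrial call ended without wild type replicate 2 (0.0674), wild type replicate 3 (0.128) or SXC mutant replicate 3 (0.152). The heat shock call ended without wild type replicate 1 (0.186), wild type replicate 3 (0.0639), or SXC mutant replicate 1 (0.0582), 2 (0.106) or 3 (0.0678). The ecdysone call ended without wild type replicate 2 (0.0838), wild type replicate 3 (0.0639), SXC mutant replicate 1 (0.115) or SXC mutant replicate 3 (0.0506). The number of lists called, 6, was 3 with quantile normalization, 3 without wild type replicate 2, 3 without wild type replicate 3, 2 without SXC mutant replicate 3 and 2 with the length trend removed.

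Lists linked to the germline and to sex did not shift as groups in the SXC mutant, though single members changed. In germline and oogenesis 6 of 40 measured genes rose, 4 fell and 30 did not pass (7 higher and 5 lower adjusted over the list alone; limma camera adjusted p = 0.749). Its median (−0.00) and mean (−0.01) were negative while the test pointed up. The piRNA pathway gene squ fell (log2 −0.87 with SE 0.11, 1.82-fold), as did png, the pan gu kinase gene of egg activation (−0.69 with SE 0.08, 1.61-fold). In the same list grk, the ligand gene gurken that patterns the egg, rose (0.40 with SE 0.07, 1.32-fold). In dosage compensation and sex determination 2 of 12 rose and 2 fell, in the same numbers adjusted over the list alone (adjusted p = 0.749), with Sxl (Sex-lethal), the master switch gene of female development, higher by 0.43 (SE 0.08). In the eggshell list 2 of 19 rose, also adjusted over the list alone (adjusted p = 0.310), namely Fcp3C (0.70, SE 0.15) and yellow-g (0.78, SE 0.19). Their calls ended without wild type replicate 1 (adjusted p = 0.0517 and 0.0920) and with no moderation (0.0892 and 0.122), and that of yellow-g without wild type replicate 3 (0.0612). Yolk proteins and uptake (4 measured, adjusted p = 0.662) and male accessory gland genes (20 measured, adjusted p = 0.976) had 0 changed members in limma, over all genes or adjusted over the list alone. In testis and spermatogenesis 1 of 37 rose and 2 fell, with 0 adjusted over the list alone (adjusted p = 0.904); the median and mean were −0.00 while the test pointed up.

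Chromatin lists behaved likewise. In the Polycomb group, to which sxc itself was assigned by its phenotype, 1 of 19 measured genes rose, 1 fell and 17 did not pass (2 higher and 2 lower adjusted over the list alone; limma camera adjusted p = 0.967). The median was −0.00 and the mean 0.02. Asx (Additional sex combs) rose by 0.52 (SE 0.09, 1.44-fold). The Hox genes (4 of 8 measured, adjusted p = 0.735) and the other classical Polycomb target genes (39 measured, adjusted p = 0.662) had 0 changed members in limma, over all genes or adjusted over the list alone. The measured Hox genes read 4.13 to 5.47 on the 9 arrays, under the median of 7.50 over genes tested. Their probe sets may detect no transcript, so the Hox result does not show that these genes were unaffected. In the Trithorax group and related chromatin factors 1 of 23 rose and 2 fell (2 higher and 4 lower adjusted over the list alone; adjusted p = 0.749). Dpy-30L1 had −0.42 (SE 0.08), and its call ended with the length trend removed (adjusted p = 0.106). Of 24 heterochromatin genes and chromatin modifiers 2 rose and 6 fell, in the same numbers adjusted over the list alone (adjusted p = 0.593), with HP1c (−0.43, SE 0.06) and the histone variant gene His2Av (−0.46, SE 0.08) among the falls. In O-GlcNAc cycling and the hexosamine pathway 2 of 8 fell, also adjusted over the list alone (adjusted p = 0.667): sxc and Gnpnat, an enzyme gene of UDP-GlcNAc synthesis (−0.34, SE 0.07), whose call ended without wild type replicate 1 (adjusted p = 0.0509). That list had a median of 0.02, with the mean (−0.17) and the test negative.

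Among stress, immune and metabolic lists, several genes changed in the SXC mutant without a shift of the list. In oxidative and metal stress 3 of 19 measured genes rose and 4 fell, in the same numbers adjusted over the list alone (limma camera adjusted p = 0.749, with a median of 0.02, a mean of −0.03 and a test pointing up). The metallothionein gene MtnA fell 2.06-fold (−1.04, SE 0.10), and the glutathione synthesis gene Gclc (0.70, SE 0.08) and the JNK phosphatase gene puc (0.70, SE 0.08) rose. In antimicrobial and humoral immunity 5 of 26 rose and 2 fell (7 and 3 adjusted over the list alone; adjusted p = 0.191), with the peptide genes DptB higher by 0.69 (SE 0.12) and AttD at −0.55 (SE 0.08). In the haemocyte list 3 of 19 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.967, median 0.03, mean −0.01). The phagocytic receptor gene eater (0.57, SE 0.11) and lectin-24A (1.03, SE 0.21) lost their calls with no moderation (adjusted p = 0.0623 and 0.0886). In glycolysis and trehalose 3 of 18 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.959). The median was −0.05 and the mean 0.00, and Gpdh1, a glycerol-3-phosphate dehydrogenase gene, rose by 0.80 (SE 0.11, 1.74-fold). In lipid metabolism 3 of 31 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.749). The desaturase gene Desat1 had 0.61 (SE 0.12) and the sterol transport gene Npc2b −0.49 (SE 0.10), both without a call when variances were not moderated (adjusted p = 0.0686 and 0.0616). In insulin, TOR and nutrient signalling 1 of 27 rose, the amino acid transporter gene slif (0.31, SE 0.08, adjusted p = 0.0326), and 0 adjusted over the list alone (adjusted p = 0.0784, but 0.0372 with ranks). The slif call ended without wild type replicate 1 (0.136) or 2 (0.0723), without any SXC mutant array (0.0605, 0.0729 and 0.0962 for replicates 1, 2 and 3), after quantile normalization (0.0515) or median centring (0.0508), with no moderation (0.0954) and with the length trend removed (0.0667). In digestive enzymes 1 of 39 rose, and 0 adjusted over the list alone (adjusted p = 0.662). Of 41 ribosomal protein genes 1 fell, also adjusted over the list alone (adjusted p = 0.976). It was RpS19b (−0.37, SE 0.08), whose call ended without wild type replicate 1 (adjusted p = 0.0529).

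Lists that mark other tissues and cell types did not shift as groups in the SXC mutant either, though single members changed. In the circadian clock list 2 of 11 measured genes rose and 0 fell, also adjusted over the list alone (limma camera adjusted p = 0.351): the clock transcription factor genes vri (0.95, SE 0.14, 1.94-fold) and Pdp1 (0.65, SE 0.10, 1.57-fold). Of 48 odorant-binding and pheromone-binding protein genes 3 fell (2 adjusted over the list alone; adjusted p = 0.789), with lush, needed for pheromone detection, at −1.05 (SE 0.10, 2.07-fold). In eye colour 1 of 18 rose and 2 fell, in the same numbers adjusted over the list alone (adjusted p = 0.976, with a median of 0.03, a mean of −0.01 and a test pointing up), and pug (pugilist) rose by 0.38 (SE 0.08). In the neuronal list 1 of 26 rose and 1 fell (1 higher and 0 lower adjusted over the list alone, adjusted p = 0.593). The synaptic vesicle priming gene unc-13, on chromosome 4, had 0.60 (SE 0.12, without a call when variances were not moderated, adjusted p = 0.0713). In the photoreceptor list 2 of 17 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.856), and the arrestin gene Arr2 had −0.53 (SE 0.10, adjusted p = 0.0583 with no moderation). The muscle list had 1 of 22 higher, and 0 adjusted over the list alone (adjusted p = 0.362). The cuticle protein list had 1 of 43 higher and 1 lower (1 and 0 adjusted over the list alone; adjusted p = 0.488). Larval serum, salivary glue and fat body genes (15 measured, adjusted p = 0.959) had 0 changed members in limma, over all genes or adjusted over the list alone.

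The comparison of the OGA mutant with the SXC mutant tested whether the responses differed, since the wild type cancels. Cell cycle and DNA replication genes were higher in the OGA mutant (21 of 36 measured, 0 lower, 31 higher adjusted over the list alone). Their median was 0.37 (limma camera adjusted p = 1.86e-13, and adjusted p = 0.933 with an estimated correlation). Among them were Mcm6 (1.09, SE 0.11), Cdc45 (0.42, SE 0.07) and Orc1 (0.41, SE 0.08). Xenobiotic detoxification genes were lower in the OGA mutant (15 of 46, with 1 higher, and 18 lower and 2 higher adjusted over the list alone). Their median was −0.12 (adjusted p = 1.65e-05, and adjusted p = 0.933 with an estimated correlation), and they included Cyp6w1 (−0.56, SE 0.06), GstE2 (−0.62, SE 0.07) and Cyp6d5 (−0.56, SE 0.09). Antimicrobial and humoral immunity genes were lower as well (7 of 26, with 2 higher, and 12 lower and 3 higher adjusted over the list alone). Their median was −0.14 (adjusted p = 0.00624, and adjusted p = 0.703 with an estimated correlation), with DptB at −0.79 (SE 0.12) and AttD in the other direction at 0.42 (SE 0.08). The number of lists called was 3, and 5 without SXC mutant replicate 3, with dim genes left out or with array quality weights.

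Single genes of this comparison mirrored the SXC mutant against wild type, which the shared SXC arrays favour by construction. Oga was lower in the OGA mutant than in the SXC mutant by a log2 difference of −1.03 (SE 0.10, 2.04-fold, limma adjusted p = 0.000459), and sxc was higher by 1.54 (SE 0.06, 2.92-fold, adjusted p = 1.88e-07). CG15399 (1.96, SE 0.22), CG11825 (1.90, SE 0.23) and CG34330 (1.74, SE 0.27) had larger positive differences than sxc, and Reg-2 (1.45, SE 0.16) a smaller difference. The genes zye (−1.81, SE 0.18), CG13031 (−1.80, SE 0.30), Cyt-b5-r (−1.77, SE 0.26), bero (−1.72, SE 0.23) and yellow-h (−1.65, SE 0.15) had the largest negative differences. With no moderation the calls of CG34330, CG13031 and Cyt-b5-r ended (adjusted p = 0.0596, 0.0679 and 0.0512). In all 1410 genes differed, 933 higher and 477 lower in the OGA mutant, and 694 higher and 612 lower after quantile normalization. A difference of at least 1.5-fold was seen in 278 of them, 133 higher and 145 lower. At an unadjusted p under 0.05 there were 3191 genes. The SXC mutant differed from both other groups in 1087 genes, 385 of them higher and 702 lower in the SXC mutant. A further 323 genes were called between the mutants but missed the threshold between the SXC mutant and wild type. Missing the threshold does not show the absence of a difference. The number of genes was 806 without OGA mutant replicate 3, 724 without SXC mutant replicate 1, 793 without SXC mutant replicate 2 and 459 with no moderation.

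Genes changed in the same direction in both mutants numbered 0 in limma, with 0.0784 lower genes by chance for independent lists. The OGA mutant had 1 call, Oga itself, so this number could not exceed 1 and does not measure a shared response. With an intensity trend and robust prior 1 gene changed in the same direction in both, Klc. It had a log2 change of 0.80 with SE 0.08 in the SXC mutant (1.74-fold, limma adjusted p = 0.000344). At an unadjusted p under 0.05 in both mutants, 154 genes had the same direction and 17 opposite directions. The shared wild-type arrays favour the same direction by construction. The changes of the mutants correlated across genes at r = 0.16 with a covariance of 0.00330, and with the length trend removed r was 0.0931 and the covariance 0.00165. In 100 simulations of unchanged mutants the shared wild-type arrays alone gave a covariance of 0.00401 (0.00376 to 0.00430). These simulations drew genes independently and gave all groups the same spread. Their range leaves out variation shared between genes, so no conclusion is drawn from the observed covariance lying below it. With each mutant set against a different wild-type array, r was 0.00255 on average (−0.15 to 0.30) and the covariance −0.000412 (−0.00524 to 0.00725).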

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

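The tests of chromosome 4 and of gene length in this part were chosen after the result was seen; those of the neighbours of sxc and of other splits of the arrays were planned. Probe sets with no single gene name were outside the comparisons of genes, and 218 of 5122 (4.26%) changed in the SXC mutant against wild type in limma, 121 higher and 97 lower. In the OGA mutant 0 of them changed, with 169 at an unadjusted p under 0.05.

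Each of the 3 comparisons was repeated with the 6 arrays split in other ways. In each, 1 of the 10 splits, the real one, gave as many genes as observed: 1 for the OGA mutant against wild type, 1549 for the SXC mutant against wild type and 1410 between the mutants, with 0 as the highest of the other splits. The 10 splits are too few for a share under 0.05.

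Genes on chromosome 4 were higher in the SXC mutant: of 46 with adequate signal, 13 rose and 0 fell, and their median change was 0.22 (95% bootstrap interval 0.08 to 0.31). The trend with gene length is argued against, since 0% of 10000 sets matched on length and level had a median as high as 0.223 (matched median 0.06). A single deviating array is argued against as well, because 3 of 3 SXC arrays had a chromosome 4 median above all other arrays (exact permutation p = 0.1, the smallest possible). An added copy of this chromosome without buffering would shift genes by 0.58 if the arrays reported its full size, above the upper bound of 0.312. That interval was drawn over genes and leaves out the spread between arrays, so such a copy is not excluded. A buffered difference in copy number, a difference in genetic background, which may exist between the groups, and an effect of the sxc mutation on this chromosome stay open and were not tested. The named genes yellow-h and unc-13 are among these genes of chromosome 4.

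Genes next to sxc, 37 with adequate signal among 25 on each side, were also higher in the SXC mutant, with 9 rises, 2 falls and a median of 0.12 (95% bootstrap interval 0.04 to 0.22). The trend with gene length is argued against, since 0.15% of matched sets had a median as high as 0.125. A shift of whole centromere ends is not seen in windows of 50 genes. Each window can reach past the genes nearest the centromere, so a shift confined to those genes is not excluded. Genes at the centromere ends of 2L, 3L, 3R and X together had a median of 0.0139, and 42.7% of matched sets were as high. The end of 2L alone had 0.10 (1.74%), against 0.01 for 3L, −0.01 for 3R and −0.02 for X. The 3L end held 11 rises and 4 falls, the 3R end 1 and 3, and the X end 6 and 7. The 2L end lies on the same chromosome as sxc, across the centromere, so it may be linked to sxc and is not a separate control. A linked stretch of chromosome around sxc that differs between the groups is a candidate explanation that stays open. So do a shift confined to the genes nearest the centromeres and an effect of the mutation on nearby genes, which were not tested. Atf6 lies in this stretch.

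Long genes were higher than short genes in both mutants. Of 10 bins of genes by length, the bin with the shortest genes had a median change of −0.06 in the OGA mutant and −0.09 in the SXC mutant, against 0.05 and 0.08 in the bin with the longest. A deviating wild-type array is argued against, since 6 of 6 mutant arrays had a slope with length above all 3 wild-type arrays. For the OGA mutant, a difference in RNA quality is argued against by the 3′ minus 5′ differences over 5 pairs of control probe sets. Of its arrays, 0 lay above the wild-type range and 2 lay inside it, although replicate 3 lay below it (0.690, against 0.765 to 0.889). For the SXC mutant it cannot be told apart from the genotype: 3 arrays lay above that range, but 0 did without GAPDH_r2, and a biological effect on long or short genes was not tested.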

How the results depend on the processing

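Removal of the length trend and all alternatives for the lists between the mutants were tests chosen after the result was seen. Signal over background was not given with the arrays, so what dim probe sets can show is not known beyond the setting that left them out. sxc kept its call in every alternative run for it, with a change of −1.51 to −1.47 when any array was left out. The Oga change was −1.05 with no moderation and no longer past the threshold, and −1.16 to −0.94 when any array was left out; the fit of only the 2 groups compared gave no call for it. The number of genes changed in the OGA mutant, 1, was 2 with an intensity trend and robust prior, 0 with no moderation, 0 with only the 2 groups compared, and 0 to 1 leaving out any array. The number in the SXC mutant, 1549, was 2824 with array quality weights, 820 with no moderation, 284 with a minimum of 1.5-fold, and 664 to 1751 leaving out any array. The number between the mutants, 1410, was 459 with no moderation, 278 with that minimum, and 724 to 1334 leaving out any array. Genes changed in the same direction in both mutants numbered 1 in place of 0 with the intensity trend and robust prior. Lists called in the OGA mutant, 2, were 4 with array quality weights, 4 with a replicate block, 0 with an estimated correlation, 0 with the length trend removed, and 0 to 5 leaving out any array. Lists called in the SXC mutant, 6, were 3 after quantile normalization, 0 with an estimated correlation, 2 with the length trend removed, and 2 to 6 leaving out any array. Lists called between the mutants, 3, were 5 with dim genes left out, 5 with array quality weights, 0 with an estimated correlation, and 3 to 5 leaving out any array. A minimum of 1.5-fold lowers a count by its construction, and fewer arrays leave fewer residual degrees of freedom; for the other changes the cause was not tested. With the replicate block, 1261 genes changed in the SXC mutant and 1130 between the mutants, and Oga was the 1 gene in the OGA mutant (limma adjusted p = 0.0369). The replicate numbers gave little sign of pairing: 1 of 9 same-number pairs, replicate 2 of wild type and of the OGA mutant, had a correlation of residuals over 0.1 (range −0.22 to 0.29), and 0 arrays correlated best with their own number in both other groups. For the genes named, 2591 results under an alternative stayed on the same side of the threshold, 497 lost the call and 0 reversed. The planned floor for values on a linear scale was not run, because the values are on a log2 scale, and list tests were not planned for the most variable probe set or for all probe sets.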

Other observations

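The tests of genes on the X chromosome were chosen after the result was seen. Genes on the X chromosome were more often lower than higher in the SXC mutant: of 1220 with adequate signal 79 rose and 215 fell in limma. Falls also outnumbered rises over all genes tested (939 and 610), and the counts on X were not tested against those of other genes. The median change on X was −0.05, against −0.02 in sets matched on gene length and level, and 100% of matched sets were as high. In the OGA mutant the median of the X genes was 0.01. The genes next to Oga, 35 with adequate signal among 25 on each side, had a median of 0.03 in the OGA mutant, where 35.3% of matched sets were as high, and 0 of these 35 changed in limma, with 1 at an unadjusted p under 0.05.

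The poly-A spike controls, 12 probe sets, had a mean of 7.35 in OGA mutant replicate 3, against 6.61 to 7.004 on the other arrays. Array quality weights were highest for wild type replicate 2 (3.31) and SXC mutant replicate 2 (2.81) and lowest for SXC mutant replicate 1 (0.411) and OGA mutant replicate 3 (0.452).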
